A study of Mus musculus with 2 samples.

How the data were processed

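The data were 2 single-cell RNA sequencing libraries, 1 control and 1 knockout, of cells from mouse subcutaneous white fat that had been sorted for live cells, made with a droplet-based 3' kit with UMIs per the labels' protocols. Groups were taken from the sample titles, and with 1 library per group neither replicates nor pairs existed. The deposited values were raw UMI counts per gene and barcode. Per the submitters' processing notes and the file headers, the authors made these counts with Cell Ranger 5.0.1 on genome build mm10; the annotation release and the settings that called barcodes as cells are not given in the sources used here. The matrices held 32285 genes, of which 78 shared a symbol with another and were kept apart by their identifiers. The position of Smpd3 was taken from GENCODE release M21, which uses the same build. How barcodes were called before deposit sets which shallow or damaged cells are present, and counts at the 3' end do not show which part of a transcript was deleted.

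Barcodes with fewer than 500 detected genes (1094 control, 128 knockout) or more than 10% mitochondrial UMIs (1299 control, 288 knockout) were left out, which removed 13.1% of control and 4.03% of knockout barcodes. Scrublet scores were computed per library. Its automatic threshold marked 1 control and 4 knockout barcodes and so had not worked, and doublets were removed as the highest scores, 0.8% per 1000 barcodes (949 control, 618 knockout). The 9202 control and 7992 knockout cells kept had medians of 4117 and 4440.5 UMIs. They were clustered together after scaling to 10000 UMIs and log transformation, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0, which gave 25 clusters. Clusters were named from 23 marker sets fixed before the data were examined, and a name ending in "-like" rests on these markers alone. A cluster was left unnamed where markers of another class led it or where over 50% of its barcodes carried markers of another lineage, which was refined after seeing the data. The limit of 50% was not applied to proliferating cells, which may be of any lineage (T or NK markers on 86.8% of barcodes of one cluster, ASPC markers on 93.8% of the other), or to erythroid-like (T or NK markers on 57.8%) and mast-like cells (B markers on 20.0%), whose own lineages were not among those counted. Classes with at least 100 cells in both libraries were compared. Proliferating cells (163 control, 160 knockout) also reached this number and were left out of the comparison of genes and lists because they mix lineages, an exception that the fixed design did not hold. Smpd3 is given for them and for macrophage-like cells, which did not reach it in knockout. The clusters within ASPC-like cells were added as groups after seeing the data.

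For each class and library UMIs were summed over cells and given as CPM, scaled by all UMIs of the class. Ratios are knockout over control with exact conditional binomial 95% intervals, sums carry exact Poisson intervals and shares exact Clopper-Pearson intervals, and all of these cover counting error only. A count of 0 was read as allowing up to 3 counts. Median depth ranged from 2332 UMIs in control B-like cells to 13046 UMIs in control Dpp4-high cells, so that ratios are more precise in progenitors than in lymphocytes. The design, the alternatives, the markers, the 26 gene lists and the rule for named genes were fixed before the data were examined.

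By that rule the 12 largest and 12 smallest ratios were named in each of the 3 classes with most cells, among genes with at least 500 UMIs in the class, a UMI in at least 10% of its cells in 1 library and the same direction in the mean over cells. In other classes the 4 largest and 4 smallest were named with at least 200 UMIs. Mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes and markers of other classes were left out. Of lists, the 2 highest and 2 lowest members were named. Some genes that the rule takes are not reported here. Other genes given beside them were chosen after their values were seen, as were the genes Prg4, Cthrc1 and Timp1 used to divide Dpp4-high cells. A list's median log2 ratio was taken over members with at least 50 UMIs, with at least 5 members, and set against 10000 random lists of the same size drawn from 20 bins of mean expression. Percentiles describe these libraries and are no test.

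A barcode was taken to carry a second lineage where it held at least 4 marker UMIs of it and at least 10% of the median of that lineage's own cells, a threshold chosen after seeing the data. Genes named without such barcodes also had to have under 25% of their CPM accounted for by the RNA of other lineages. Alternatives were a minimum of 200 or 1000 genes, a mitochondrial maximum of 5% or 20%, no removal of doublets, resolutions of 0.5 and 2.0, clustering of each library on its own, TMM scaling, the mean over cells, thinning to 1500 UMIs and member minimums of 10 and 200 UMIs. Leaving out barcodes with a second lineage, counting every lineage of a barcode, and TMM scaling and the mean over cells for Smpd3 were added after seeing the data.

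The calculations were tested on simulated data with 100 genes changed 2-fold each way. Median ratios of 2.0 and 0.502 in ASPC-like, 1.99 and 0.505 in T-like, 2.0 and 0.503 in B-like and 2.02 and 0.507 in monocyte-like cells were recovered, and intervals covered the simulated ratio for 91% to 97% of these genes. Of 100 random lists per class, 92% to 95% lay inside the central 95%. Genes were simulated independently there, so this does not cover lists whose members vary together. The analysis used Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM scaling alone.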

Results

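Single-cell RNA sequencing was carried out on the stromal vascular fraction of mouse subcutaneous white fat, the mixture of progenitor, endothelial and immune cells that remains once adipocytes have been removed from digested tissue. The series held 1 control library and 1 knockout library, each from 12-week-old males kept for 2 weeks on chow with doxycycline at 600 mg/kg, and dead cells had been excluded by sorting. Control mice carried floxed Smpd3 and a doxycycline-responsive transactivator under the adiponectin promoter. Knockout mice also carried Cre recombinase under the control of that transactivator, which places the deletion in adipocytes. The series concerns messenger RNAs that adipocytes obtain from neighbouring cells, and these libraries show the neighbouring cells. The control library held 11680 barcodes and 67211484 unique molecular identifiers (UMIs), with a median of 3824 UMIs and 1333 genes per barcode. The knockout library held 8972 barcodes and 53738197 UMIs, with medians of 4526 UMIs and 1651.5 genes. After filtering, 9202 control and 7992 knockout cells remained. With 1 library per genotype there was no replicate and no test between genotypes, so each comparison is between these 2 libraries. Intervals are exact 95% intervals and cover counting error only.

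Smpd3, the targeted gene (ENSMUSG00000031906), encodes neutral sphingomyelinase 2, which releases ceramide from sphingomyelin and acts in the formation of secreted vesicles. Among the classes measured, its transcript was most abundant in adipose stem and progenitor-like cells (ASPC-like), and within them in Dpp4-high cells, a progenitor state marked by Dpp4 and Pi16. In Dpp4-high cells Smpd3 was higher in the knockout library, at 381 CPM (UMIs of the gene relative to all UMIs of the group; 1638 UMIs, 1560 to 1719, in 371 cells) against 239.9 CPM in control (3957 UMIs, 3835 to 4082, in 1217 cells), a ratio of 1.59 (1.5 to 1.68). The ratio was 0.914 (0.843 to 0.991) in Dpp4-high cells without a UMI of Prg4, Cthrc1 or Timp1 and 1.80 (1.63 to 1.99) in those with one. These genes were chosen for being lower in knockout. Committed ASPC-like cells, the state closer to adipocytes, held 19.5 CPM in knockout (85 UMIs in 387 cells) and 9.68 CPM in control (38 UMIs in 330 cells), a ratio of 2.02 (1.36 to 3.04). Over all ASPC-like cells, of which Dpp4-high cells made up a smaller share in knockout, the levels were 199 and 196 CPM, a ratio of 1.02 (0.962 to 1.08).

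A UMI of Smpd3 was found in 82.2% (77.9 to 86.0) of knockout and 72.5% (69.9 to 75.0) of control Dpp4-high cells, at median depths of 11399 and 13046 UMIs. In T-like cells, which should lack the gene, the shares were 0.41% and 0.20% at median depths of 3787 and 3646 UMIs. With each Dpp4-high cell thinned to 1500 UMIs, a depth reached by 370 knockout and 1215 control cells, the shares were 33.2% and 27.3% and the ratio of CPM was 1.36 (1.15 to 1.61). In B-like cells 34 UMIs in knockout and 9 in control gave 3.56 and 1.48 CPM, a ratio of 2.41 (1.13 to 5.70). That ratio was 6.10 (1.53 to 52.95) with at least 1000 genes, and its interval reached 1 with a mitochondrial maximum of 5%, at 1.39 (0.372 to 6.30), and with cells thinned, at 2.38 (0.907 to 7.34). Thinning also brought the interval in committed ASPC-like cells to 1, at 1.56 (0.528 to 5.13; 11 and 6 UMIs). T-like cells held 6 and 5 UMIs, endothelial-like cells 6 and 4, monocyte-like cells 17 and 38, macrophage-like cells 6 and 29 and dendritic-like cells 2 and 0, and no difference was detectable at these counts. With at least 200 genes endothelial-like cells held 14 and 4 UMIs, a ratio of 4.92 (1.54 to 20.5). With barcodes that carry markers of a second lineage left out they held 0 and 4. Proliferating cells, which mix lineages, held 21 UMIs in knockout and 52 in control (8.08 and 18.4 CPM), a ratio of 0.439 (0.251 to 0.741). ASPC markers were on 3.12% of knockout and 34.97% of control proliferating cells, so that ratio also carries the difference in this share. No UMI was found in the 240 knockout and 149 control NK-like cells, which allows levels of up to 2.81 and 5.15 CPM (upper ends of the exact Poisson intervals). In mm10 the gene lies on the minus strand of chromosome 8 from 106252548 to 106337988, with 9 exons in transcript Smpd3-201 and the 3' untranslated region from 106252548 to 106255261. Reads of a 3' assay come mostly from the end of a transcript, which may lie outside the deleted part, and adipocytes were not among the classes, so Smpd3 here does not check the genotype labels.

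**Figure D1:**
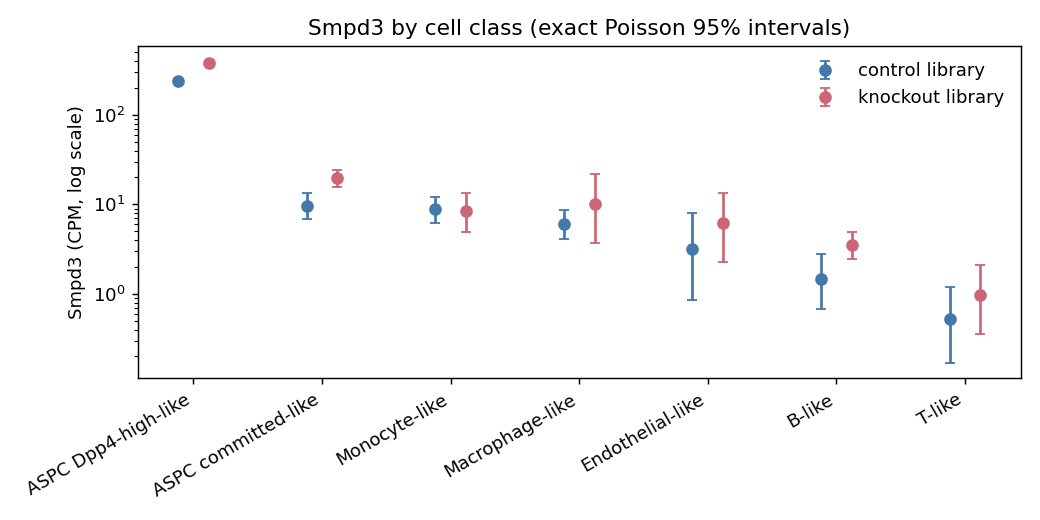
Smpd3 in CPM on a log axis for 7 groups of cells in the control and knockout libraries, where points are values and bars exact Poisson 95% intervals for counting error. Dpp4-high ASPC-like cells stood at 239.9 CPM in control and 381 CPM in knockout, above the other groups drawn.

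The cell composition differed between the libraries. B-like cells made up 37.2% of knockout (2970 cells; 36.1 to 38.2) and 25.4% of control cells (2339 cells; 24.5 to 26.3), whereas T-like cells made up 18.2% (1452 cells; 17.3 to 19.0) and 27.4% (2517 cells; 26.4 to 28.3). The T-like share leaves out unnamed clusters 6, 8 and 14, whose markers supported T cells best. These held 10.7%, 5.38% and 1.31% of knockout cells and 0.011%, 3.83% and 1.98% of control cells. Counted as T-like, they would make the share higher in knockout, though 99.5% of barcodes in cluster 6 also carried B cell markers. ASPC-like cells were 9.48% of knockout (758 cells; 8.85 to 10.1) and 16.8% of control cells (1547 cells; 16.1 to 17.6). Macrophage-like cells were 1.01% of knockout (81 cells; 0.806 to 1.26) and 6.22% of control cells (572 cells; 5.73 to 6.73), and monocyte-like cells 2.95% (236 cells) and 6.59% (606 cells). NK-like cells were 3.0% and 1.62%, dendritic-like cells 2.89% and 2.13%, endothelial-like cells 1.73% and 2.33%, and neutrophil-like cells 0.676% and 1.48%.

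Of the cells that were not T-, B- or NK-like, ASPC-like cells were 22.8% of 3330 in knockout and 36.9% of 4197 in control, and macrophage-like cells were 2.43% and 13.6%. With the unnamed clusters whose markers supported T or B cells best left out as well (6, 8, 14 and 22, the last a cluster of 45 knockout and 2 control cells with endothelial genes among its leading genes), ASPC-like cells were 39.98% of 1896 and 42.3% of 3660 cells and macrophage-like cells 4.27% and 15.6%. Within ASPC-like cells, Dpp4-high cells were 48.9% of knockout (45.3 to 52.6) and 78.7% of control cells (76.5 to 80.7). A split made without the 3861 genes that differed over 2-fold between the libraries gave 49.6% and 78.2%. The largest cluster of B-like cells was cluster 5 in knockout, with 1226 cells, and cluster 3 in control, with 1211, and for T-like cells these were cluster 1 with 819 and cluster 2 with 1330. Dendritic-like cells lay in 3 clusters, of which cluster 18, with Xcr1 and Clec9a, held 77 of 231 knockout and 27 of 196 control cells, and cluster 19, with Siglech, 35 and 56. Gene values for these 3 classes also carry the difference in the shares of their clusters. The labels do not say how many mice or cells went into each library or whether the lymph node of the depot was removed, and each of these would act on the shares of lymphocytes. The sort for live cells and the filters act on these shares too, since 11.1% of control and 3.21% of knockout barcodes exceeded 10% mitochondrial UMIs. Unnamed clusters 6, 8, 12, 14 and 22 held 10.7%, 5.38%, 2.40%, 1.31% and 0.563% of knockout cells and 0.011%, 3.83%, 1.98%, 1.98% and 0.022% of control cells.

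**Figure D2:**
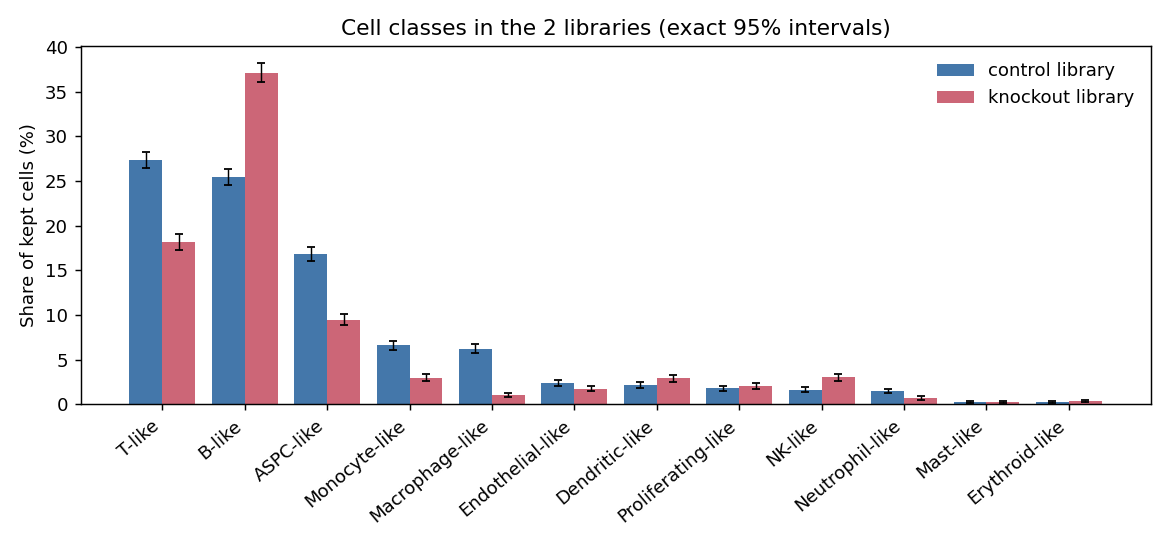
Share of kept cells, in percent, in each named class of the control and knockout libraries, with exact binomial 95% intervals for counting error. B-like cells were 25.4% of control and 37.2% of knockout cells, and macrophage-like cells 6.22% and 1.01%.

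Markers of a second cell lineage, mostly of B or T cells, were carried by 28.1% of knockout barcodes (2245 of 7992; 27.1 to 29.1) and 4.33% of control barcodes (398 of 9202; 3.92 to 4.76). In knockout these were 57.4% of ASPC-like, 58.4% of dendritic-like, 55.1% of monocyte-like, 52.2% of endothelial-like and 50.6% of macrophage-like barcodes, against 11.9%, 13.8%, 5.12%, 3.74% and 6.82% in control. B cell markers were on 39.6% and T or NK cell markers on 25.9% of knockout ASPC-like barcodes. Cluster 6, which held 854 knockout barcodes and 1 control barcode, carried both T and B cell markers. In knockout, the 1191 barcodes with T and B markers had a median of 6706 UMIs, those with B markers alone 2519 and those with T markers alone 4029.5. With barcodes of a second lineage left out, B-like cells were 50.7% of knockout and 26.4% of control cells and T-like cells 24.99% and 28.5%. The other named classes kept the direction of their difference except 3 that were then lower in knockout: dendritic-like cells (1.67% of knockout and 1.92% of control cells), proliferating cells (1.48% and 1.59%, from 2.00% and 1.77%) and erythroid-like cells (0 and 1 cell, from 26 and 19). Gene values below are given with such barcodes left out where stated, a selection chosen after seeing the data.

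**Figure D3:**
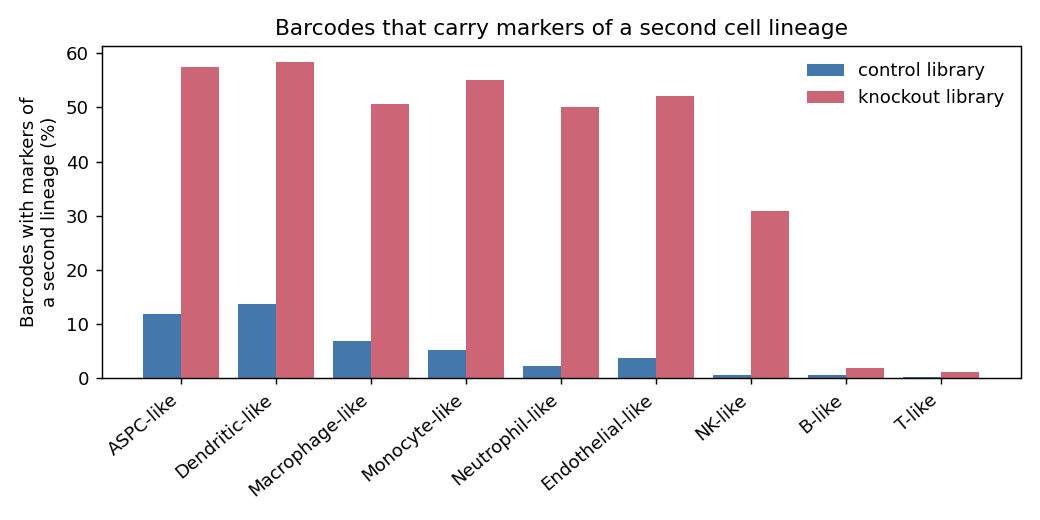
Share of barcodes, in percent, that carried markers of a second cell lineage, by class and library. In ASPC-like barcodes the share was 57.4% in knockout and 11.9% in control, and in B-like barcodes 1.92% and 0.51%.

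In Dpp4-high ASPC-like cells transcripts of several matrix proteins, protease inhibitors and chemokines were lower in the knockout library. Cthrc1, a secreted protein of activated fibroblasts, stood at 12.8 CPM in knockout and 429 CPM in control, Prg4, the lubricating proteoglycan lubricin, at 17.5 and 506 CPM, and Timp1, an inhibitor of matrix metalloproteinases, at 19.6 and 344 CPM. Mmp3, a matrix metalloproteinase, was lower (85.0 and 739 CPM), as were Serpina3n, a protease inhibitor (31.9 and 230.1 CPM), Bgn, the proteoglycan biglycan (86.1 and 390 CPM), and Cav1, the main protein of caveolae (23.0 and 110 CPM). The chemokines Cxcl13 (71.9 and 384 CPM) and Ccl8 (19.6 and 294 CPM) were also lower, with ratios of 0.187 and 0.066, and Ccn5 and Ccn2, matricellular proteins, had ratios of 0.106 and 0.206. At least 1 UMI of Prg4, Cthrc1 or Timp1 was found in 26.2% (21.8 to 30.9) of knockout and 76.3% (73.8 to 78.6) of control Dpp4-high cells, against 0.96% and 2.66% of T-like cells at the depths given above. At 1500 UMIs per cell the shares were 7.03% and 47.7%, against 0.42% and 1.24%.

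The genes with the largest ratios in these cells were lymphocyte genes, among them Ly6d (17.3), H2-Ab1 (17.2), H2-Aa (16.5) and Cd74 (15.4), in barcodes of which many carried markers of a second lineage. With those barcodes left out, which leaves 158 knockout and 1093 control cells, Sult1e1, an oestrogen sulfotransferase, was higher in knockout at 155 against 43.5 CPM, a ratio of 3.57 (3.06 to 4.15). Bmp2, a bone morphogenetic protein, had a ratio of 3.36 (2.87 to 3.93), Krtdap 3.29, Igfbp3, an insulin-like growth factor binding protein, 2.96, Chst1 2.75 and Abca8a 2.60. Fgf2, a fibroblast growth factor, stood at 199 against 86.6 CPM and Edn1, the precursor of endothelin 1, at 204 against 92.8 CPM. Smpd3 was at 502 against 252 CPM in these cells, a ratio of 1.99 (1.84 to 2.15). Among the genes that were lower, Cthrc1 (0.021), Prg4 (0.037), Timp1 (0.071), Mmp3 (0.15) and Bgn (0.144) kept that direction.

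**Figure D4:**
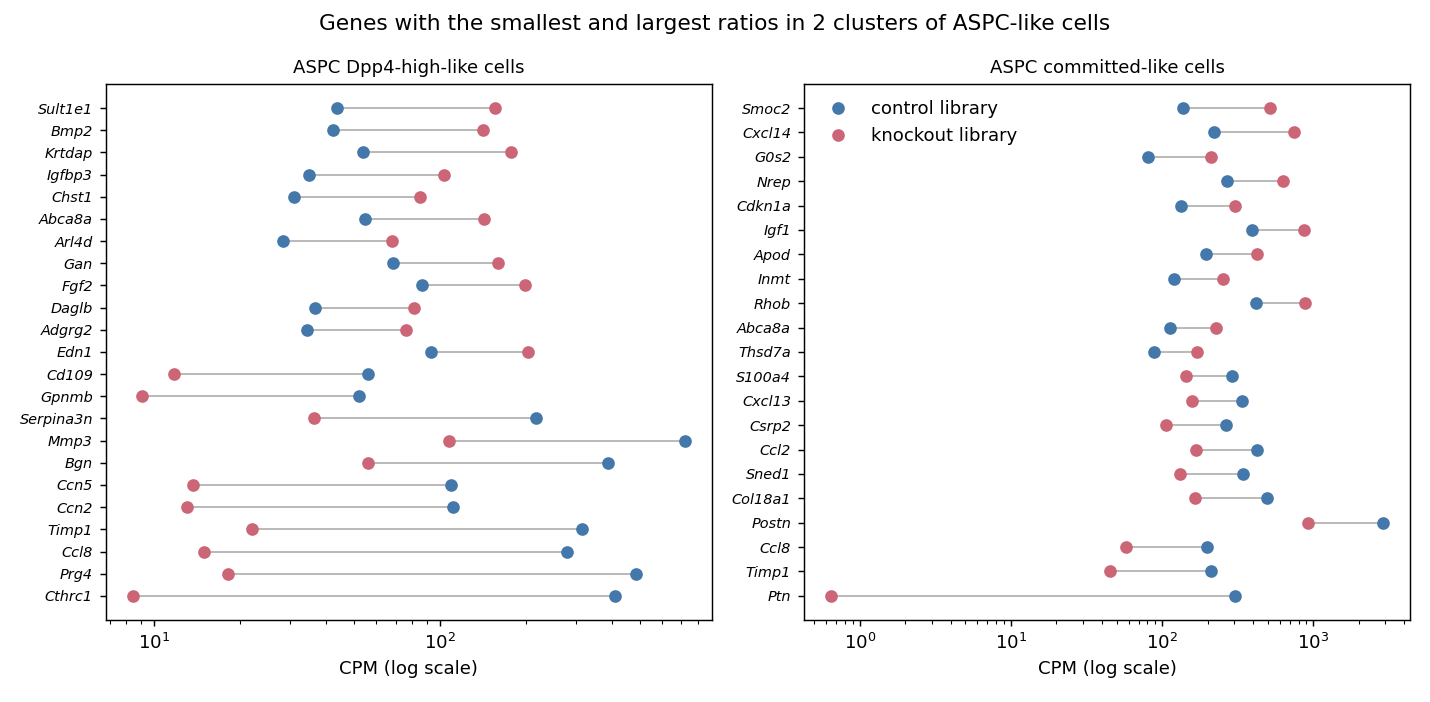
Genes with the smallest and largest ratios in Dpp4-high (left) and committed (right) ASPC-like cells, as CPM on a log axis in the control and knockout libraries, without barcodes of a second lineage. Cthrc1 was lower in knockout in Dpp4-high cells with a ratio of 0.021, Smoc2 was higher in committed cells with a ratio of 3.77, and Cxcl14 is among the genes that lead the committed cluster.

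Gene lists were compared by the median log2 ratio of their members, with its percentile among 10000 random lists matched on expression, which describes these libraries and is not a test. In Dpp4-high cells 13 of 25 lists lay outside the central 95% of random lists. Random lists were drawn gene by gene, so 5% outside is no standard for lists whose members vary together. The list of fibrillar collagens and matrix had a median of -0.55 (percentile 0.0), with 27 of 29 members lower in knockout, among them Timp1 and Mmp3, and 2 higher, Timp3 and Fbn1. Without barcodes of a second lineage its median was -0.32 (percentile 0.0; 23 members lower), with Col1a1, a chain of type I collagen, at 13916 against 19409 CPM and Col3a1 at 23244 against 29951 CPM. In cells without a UMI of Prg4, Cthrc1 or Timp1 it was -0.27, and -0.03 without barcodes of a second lineage as well, both below the range. The list was also low outside ASPC-like cells, at -0.62 in B-, -0.51 in T-, -0.69 in NK- and -0.72 in dendritic-like cells (all at percentile 0.0). It was 0.23 (percentile 97.51) in endothelial-like cells and inside the range in monocyte-like cells. ASPC markers, some of them collagens, moved the same way as background. Their level relative to ASPC-like cells was 0.356% in knockout and 0.541% in control B-like cells. It was 0.272% and 0.384% in T-, 0.181% and 0.319% in NK- and 0.156% and 0.216% in dendritic-like cells. In endothelial-like cells it was 3.55% and 0.565%. The list is therefore not shown to differ in the cells of these classes themselves. Lysosomal genes had a median of -0.29 (percentile 0.01; 18 of 23 lower), with Ctsk, the collagen-degrading cathepsin K, at 146 against 269 CPM and Npc2, a cholesterol carrier, at 394 against 681 CPM without barcodes of a second lineage. Glycolysis genes had a median of -0.22 (percentile 0.23; 10 of 15 lower, Hk2 and Slc16a3 the lowest), and they lay at percentile 28.7 with cells thinned to 1500 UMIs. Interferon response genes had a median of -0.16 (percentile 0.06; 16 of 27 lower, Oas1a and Ifi44 the lowest), with percentile 10.1 after thinning.

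Other lists were higher in Dpp4-high cells of the knockout library. Genes of the immediate early and dissociation stress list had a median of 0.26 (percentile 99.9; 24 of 28 higher), and without barcodes of a second lineage Klf2, a transcription factor, stood at 1399 against 668 CPM and Fos at 4259 against 3119 CPM. In Dpp4-high cells without a UMI of Prg4, Cthrc1 or Timp1 the median was 0.09, inside the range (percentile 90.3), and 0.26 (percentile 100) with barcodes of a second lineage left out as well. RNA-binding proteins linked to vesicle RNA had a median of 0.37 (percentile 100; 20 of 23 higher), with G3bp1 and Ago2 the highest and Mvp and Pabpc1 the lowest. Cytosolic ribosomal proteins had a median of 0.38 (percentile 100; 29 of 30 higher), and 0.12 inside the range (percentile 86.6) without barcodes of a second lineage. Mitochondrially encoded transcripts, on which the filter of cells acts, had a median of -0.23 inside the range (percentile 5.66; 11 of 13 lower) and -0.30 (percentile 0.21; 13 of 13 lower) without such barcodes. On the same terms 13 of 13 were also lower in committed ASPC-like, monocyte-like and dendritic-like cells. MHC class II genes had a median of 3.88 (percentile 100; 10 of 10 higher), and of their knockout level without barcodes of a second lineage the RNA of other lineages would give 31.0% for H2-Ab1 and 52.1% for Cd74. That estimate takes macrophage- and monocyte-like cells as the only myeloid sources and leaves out dendritic-like cells. The rest is therefore not shown to come from progenitors. Genes of extracellular vesicle biogenesis and release lay inside the range of random lists in these cells, with a median of 0.00 (percentile 5.71; 16 higher and 16 lower), as did those of sphingolipid and ceramide metabolism at 0.17 (percentile 44.5). Caveolae and endocytic uptake genes had a median of -0.17 (percentile 0.54; 11 of 19 lower, Cav1 and Cav2 the lowest), and -0.05 inside the range (percentile 3.76) without barcodes of a second lineage. TMM scaling would move all log2 ratios by -0.24 in Dpp4-high, -0.11 in committed, -0.14 in B-like and -0.17 in T-like cells and leaves the percentiles as they are.

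**Figure D5:**
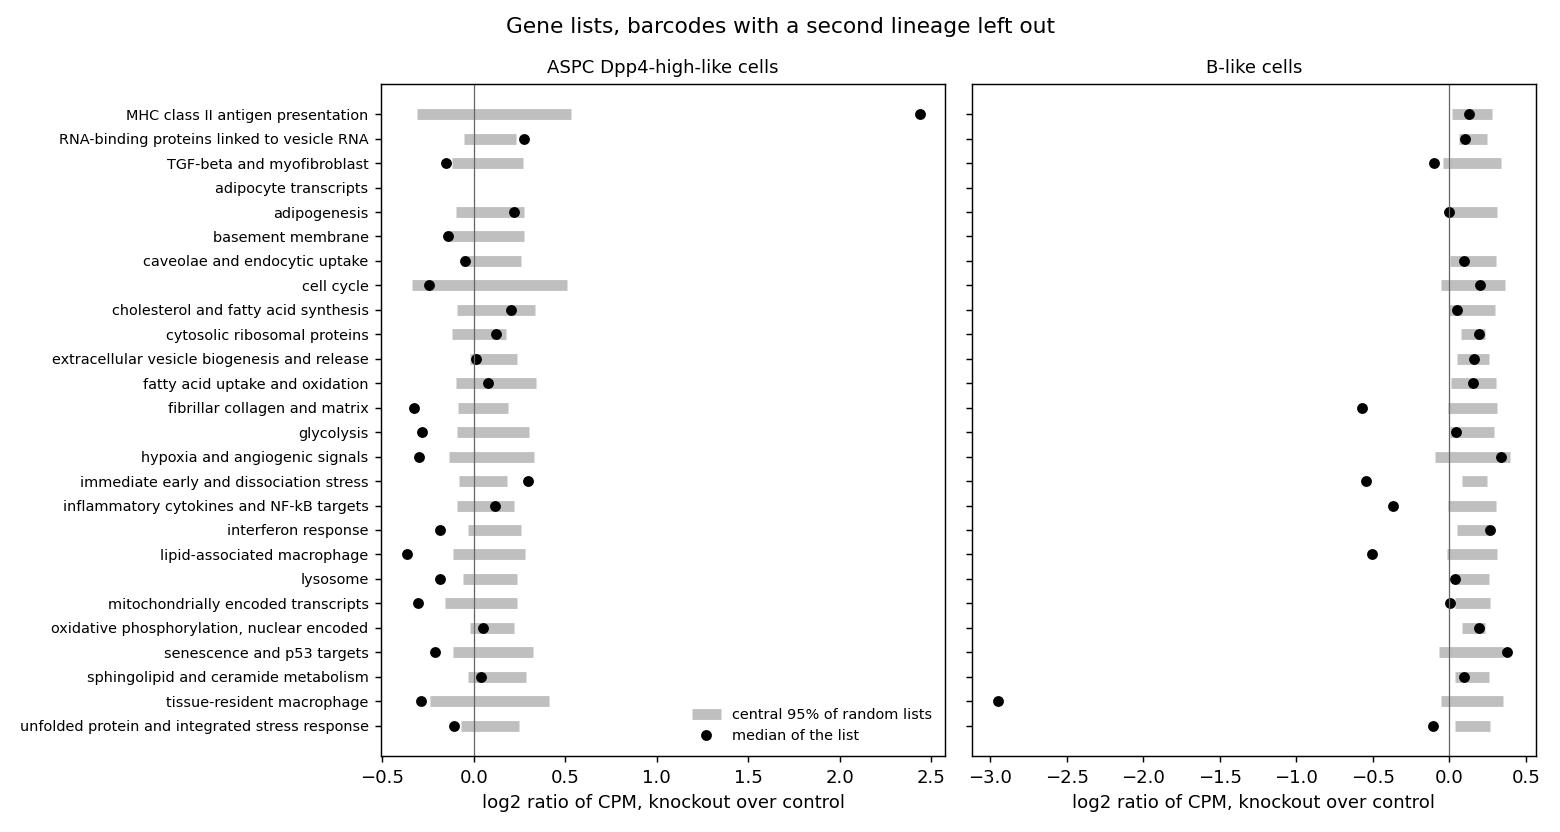
Median log2 ratio of CPM, knockout over control, of each gene list (points) in Dpp4-high ASPC-like cells and B-like cells, without barcodes of a second lineage, with bars for the central 95% of matched random lists. Fibrillar collagen and matrix lay at -0.32 in Dpp4-high cells, and immediate early genes at 0.30 in Dpp4-high and -0.54 in B-like cells.

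In committed ASPC-like cells Ptn, the growth factor pleiotrophin, was lower in knockout, at 8.97 against 272 CPM, a ratio of 0.033. Postn, the matrix protein periostin, stood at 831 against 2967 CPM, Col18a1, a basement membrane collagen, at 149 against 504 CPM, and Mgp, the matrix Gla protein, at 43.7 against 170.1 CPM. Fgf10, a fibroblast growth factor, was at 69.0 against 185 CPM and the monocyte chemokine Ccl2 at 163 against 421 CPM. Without barcodes of a second lineage, which leaves 165 knockout and 270 control cells, Smoc2, a matricellular protein, was higher at 517 against 137 CPM (ratio 3.77) and Igf1, an insulin-like growth factor, at 868 against 394 CPM (2.20). G0s2, an inhibitor of the triglyceride lipase ATGL, had a ratio of 2.62, the cell cycle inhibitor Cdkn1a 2.26 and Apod, a lipid-binding protein, 2.15. Timp1 and Ccl8 were lower here too, with ratios of 0.247 and 0.264 over all committed cells.

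Interferon response genes had a median of -0.23 in committed cells (percentile 0.01; 19 of 26 lower), and without barcodes of a second lineage Cxcl10, an interferon-induced chemokine, stood at 307 against 559.8 CPM and Ifit3 at 84.1 against 59.0 CPM. Fatty acid uptake and oxidation genes had a median of -0.25 (percentile 0.02; 14 of 18 lower), with Ucp2 and Cpt1a the highest. Nuclear genes of oxidative phosphorylation had a median of -0.10 (percentile 0.77; 23 of 30 lower). The matrix list had a median of -0.19 (percentile 0.09), and 0.06 inside the range (percentile 84.1) without barcodes of a second lineage. Such barcodes were 57.4% of knockout and 18.2% of control committed cells. Leaving them out took the lists outside the range from 13 of 25 to 8 of 23, and those below it from 11 to 5. The fatty acid and oxidative phosphorylation medians are given with these barcodes kept, so dilution by lymphocyte RNA is not excluded for them.

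Over all ASPC-like cells, for which most control cells lay in the Dpp4-high cluster and most knockout cells in the committed cluster, the values also carry the difference in those shares. Prg4 stood at 12.1 CPM in knockout and 421 CPM in control, Cthrc1 at 17.8 and 365 CPM, Timp1 at 38.9 and 323 CPM and Ccn2 at 15.5 and 90.8 CPM. Cd109, Tdo2, Mcub, Chrdl1 and Sfrp4, a secreted Wnt modulator, had ratios between 0.234 and 0.298. The genes with the largest ratios were again lymphocyte genes, Bank1 (17.2) and Ly6d (16.6) first, of whose knockout level the RNA of other lineages would give 88.6% and 113.4%. Penk, the enkephalin precursor, had a ratio of 4.27 and Trf, transferrin, 3.83 without barcodes of a second lineage. Adipogenesis genes had a median of 0.33 (percentile 99.5; 18 of 24 higher, Apoe and Pparg the highest), and vesicle biogenesis genes 0.01 (percentile 9.17). The 11 lists outside the range included the matrix list, with a median of -0.45 (percentile 0.0; 24 of 30 lower).

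In B-like cells immediate early genes were lower in the knockout library. Egr1, a transcription factor induced by stimulation, stood at 54.4 against 142 CPM (ratio 0.383), Fosb at 66.1 against 168 CPM (0.393) and Plk2, a polo-like kinase, at 37.7 against 107 CPM (0.352). Fos, Nr4a1, a marker of recent antigen receptor signalling, and Myc had ratios of 0.42, 0.412 and 0.40 with barcodes of a second lineage left out. The immediate early and dissociation stress list had a median of -0.56 (percentile 0.0), with 25 of 28 members lower, Egr2 and Ier3 the lowest and Hspe1 and Klf2 the highest. Ddit4, an inhibitor of mTORC1 signalling, was higher at 93.3 against 41.0 CPM, a ratio of 2.28 (1.98 to 2.63), and Gimap7, a GTPase of lymphocytes, at 103 against 51.3 CPM. Clec2i, Rnase6, Id3 and Trim5 had ratios between 1.68 and 1.72. Gm42418, a gene model in a ribosomal RNA repeat, took 2.71% of knockout and 6.94% of control UMIs over all kept cells, and Lars2, whose counts are known to move with it, had ratios between 0.316 and 0.603 in the 7 classes measured.

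Of 24 lists, 12 lay outside the range in B-like cells. Unfolded protein and integrated stress response genes had a median of -0.10 (percentile 0.01; 15 of 18 lower), with Ppp1r15a at 80.3 against 152 CPM. Interferon response genes had a median of 0.30 (percentile 99.6; 21 of 26 higher), a position that reversed when each library was clustered on its own (percentile 0.02). With the mean over cells no list lay above the range in B-like cells. The class also includes cluster 21, led by the interferon response genes Ifit3, Ifi209 and Oasl1, with 54 knockout and 10 control cells. The median therefore also carries the difference in the share of that cluster. Vesicle biogenesis genes lay inside the range at 0.15 (percentile 42.7), as did sphingolipid genes at 0.10 (percentile 19.3). Transcripts of macrophages, which these cells should lack, were lower in B-like and T-like cells of the knockout library, where macrophage-like cells were 1.01% against 6.22% in control. Ccl8 had ratios of 0.023 and 0.033, and in T-like cells it stood at 2.11 against 64.2 CPM, Apoe at 13.8 against 91.8 CPM, Lyz2 at 19.0 against 62.5 CPM and C1qa at 2.60 against 30.1 CPM. The tissue-resident macrophage list had medians of -2.80 in B-like and -2.04 in T-like cells, where 12 of 12 and 11 of 11 members were lower. In T-like cells the RNA of other lineages would give 105% of the control and 124.2% of the knockout level of Apoe, 136.8% and 150.4% of Lyz2, 91.9% and 130.1% of C1qa, and 34.6% of the control level of Ccl8.

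In T-like cells immediate early genes were also lower in the knockout library. Jun stood at 99.4 against 199 CPM (ratio 0.498), Fosb at 39.2 against 78.0 CPM (0.503) and Hspa1a, an inducible heat shock protein, at 67.7 against 131 CPM (0.517). The immediate early and dissociation stress list had a median of -0.22 (percentile 0.0; 24 of 28 lower), with the heat shock genes Hspe1 (1.22) and Hsp90ab1 (1.04) the highest, and unfolded protein and integrated stress response genes -0.07 (percentile 0.0; 11 of 17 lower). Ikzf2, the transcription factor Helios, was higher at 45.2 against 27.5 CPM (1.64), and Hypk, Pigp and Tmem245 had ratios of 1.69, 1.57 and 1.55. H2-Ab1 (2.54), Cd74 (2.31) and H2-Aa (2.12) were higher as well, next to an Igkc level, a B cell transcript, of 66.9 against 10.7 CPM in these cells. Vesicle biogenesis genes lay inside the range at 0.13 (percentile 25.3), and 8 of 24 lists lay outside it.

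Monocyte-like cells of the knockout library held less of the transcripts of tissue-resident macrophages. Cbr2, a carbonyl reductase of resident macrophages, stood at 26.0 against 187 CPM (ratio 0.139), Gas6, a ligand of receptors for apoptotic cells, at 10.8 against 68.6 CPM (0.158) and Ccl8 at 12.3 against 165 CPM (0.074). The tissue-resident macrophage list had a median of -0.88 (percentile 0.0; 11 of 13 lower), with Cd163 and Cbr2 the lowest and Retnla and Mgl2 the highest. The background was also lower in knockout, as T-like cells, which should lack these transcripts, held 2.11 CPM of Ccl8 in knockout and 64.2 CPM in control, and 0.16 and 8.76 CPM of Cbr2. The lysosome list had a median of -0.55 (percentile 0.0; 21 of 23 lower), and without barcodes of a second lineage Ctsl, the protease cathepsin L, stood at 354 against 750.1 CPM. Interferon response genes had a median of -0.65 (percentile 0.0; 21 of 27 lower), and -0.24 (percentile 0.09; 18 of 27 lower) without barcodes of a second lineage, which leaves 106 knockout and 575 control cells. Without those barcodes Cxcl10, a member of that list, was higher at 422 against 52.8 CPM, a ratio of 8.0 (6.67 to 9.6), and Ccl7 was lower at 41.2 against 314 CPM. Over all monocyte-like cells vesicle biogenesis genes had a median of -0.17 (percentile 1.54; 24 of 30 lower, Ehd4 and Flot2 the lowest), sphingolipid genes -0.24 (percentile 0.15; 21 of 28 lower) and caveolae and endocytic uptake genes -0.41 (percentile 0.1; 11 of 15 lower). RNA-binding proteins linked to vesicle RNA had a median of 0.29 (percentile 99.9; 18 of 23 higher). These 4 lists lay inside the range without barcodes of a second lineage, at percentiles of 8.04, 3.32, 8.44 and 92.6.

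In NK-like cells without barcodes of a second lineage, Ssh2 (ratio 1.87), Tcf12 (1.82) and Bcl11b (1.76) were higher in the knockout library. T and NK cells were counted together as a lineage, so NK-like barcodes that also held a T cell were not left out. Bcl11b is among the leading genes of T-like cluster 2, so its ratio is not shown to come from NK cells. Cell cycle genes had a median of -0.49 over all NK-like cells (percentile 0.0; 8 of 9 lower), with the replication genes Mcm2 and Hells at ratios of 0.474 and 0.479 without barcodes of a second lineage. The immediate early list had a median of -0.23 (percentile 0.0; 19 of 25 lower) and glycolysis genes -0.25 (percentile 0.06; 9 of 11 lower). In dendritic-like cells, taken over clusters in differing shares, MHC class II genes had a median of 0.45 (percentile 99.8) and lysosomal genes -0.24 (percentile 0.23; 17 of 19 lower). Vesicle biogenesis genes had a median of -0.11 there (percentile 1.59; 16 of 27 lower), and 0.06 inside the range (percentile 72.2) without barcodes of a second lineage. Without such barcodes, which leaves 96 knockout and 169 control dendritic-like cells, H2-Ab1 stood at 4128 against 2135 CPM, Il1b at 222 against 68.6 CPM and Ctsl at 76.0 against 361 CPM. In endothelial-like cells on the same terms, 66 knockout and 206 control cells, Txn1, a thioredoxin, had a ratio of 2.10 and Depp1 1.99, while Itih5 (0.195), Tiparp (0.214) and Mt1, a metallothionein (0.333), were lower. Their immediate early list had a median of -0.26 (percentile 0.94) over all endothelial-like cells and -0.22 (percentile 0.01) on those terms.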

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

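The 3 tests in this part were all chosen after the result was seen. In the knockout library 28.09% of kept barcodes carried markers of 2 lineages, above the 4.33% of the control library, and they stand out because no comparison of the study's design uses them. Free RNA is argued against by the amounts: of 443 knockout ASPC-, endothelial- and monocyte-like barcodes that carried B cell markers, 85.55% held at least 50% of the B marker UMIs of a typical B-like cell, whose median was 18. Selective attachment of B cells to T cells is argued against because the share with B cell markers among T or NK barcodes (38.1%) was 0.946 times that among ASPC barcodes (40.3%), where a value of at least 1.5 had been set for it. What stays open is co-capture of cells at random, and a biological explanation by genotype, which 1 library per group cannot test. For co-capture, the highest share with B cell markers among 6 classes was 1.319 times the lowest. Knockout erythroid-like (69.2% of 26) and mast-like barcodes (45.0% of 20) were not among these classes. Even shares also do not settle the rate. The doublet rule removed 7.18% of scored knockout barcodes, and 28.09% of those kept still carried markers of 2 lineages.

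Cluster 6, with T cell leading genes and B cell markers on 99.5% of its barcodes, held 10.686% of knockout and 0.011% of control barcodes, and the knockout share stood out against the control library.

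The immediate early and dissociation stress list lay in opposite directions in 2 cell types. Its median log2 ratio was 0.31 in ASPC-like and -0.56 in B-like cells, a difference of 0.866 that was not tested. Within ASPC-like cells the list lay outside the range in Dpp4-high cells (0.26) and inside it in committed cells. The value over all ASPC-like cells also carries the differing shares of these states.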

How the results depend on the processing

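Leaving out barcodes with a second lineage, counting every lineage of a barcode, and for Smpd3 the TMM scaling were tried only after the result was seen. Shares are differences in percentage points, knockout minus control. Those given here kept their direction under every setting run, as did the ratio of Smpd3 in Dpp4-high cells. Dividing those cells by Prg4, Cthrc1 and Timp1 was not among these settings and gave a ratio of 0.914 in cells without a UMI of them. Adding unnamed clusters 6, 8 and 14 to T-like cells was not among them either and would reverse the T-like difference. Every lineage of a barcode was counted for ASPC- and B-like cells alone. The main differences were -7.33 for ASPC-, 11.74 for B-, -9.18 for T-, -5.20 for macrophage- and -3.63 for monocyte-like cells and -29.72 for the Dpp4-high share of ASPC-like cells. With at least 1000 genes they were -9.94 for ASPC-, 14.06 for B-, -10.80 for T-, -6.78 for macrophage- and -4.86 for monocyte-like cells. With a mitochondrial maximum of 5% they were -10.80 for ASPC-, 8.80 for B-, -4.16 for macrophage- and -1.95 for monocyte-like cells and -42.50 for the Dpp4-high share. With each library clustered on its own they were -3.70 for ASPC-, 9.84 for B- and -7.57 for T-like cells and -51.64 for the Dpp4-high share, because the committed cluster of control was not named ASPC-like there. Without barcodes of a second lineage they were -9.86 for ASPC-, 24.26 for B-, -3.53 for T- and -4.69 for monocyte-like cells, and with every lineage counted -9.87 for ASPC- and 21.12 for B-like cells. The ratio of Smpd3 in Dpp4-high cells, 1.589 in the main setting, was 1.990 without barcodes of a second lineage, 1.747 with a mitochondrial maximum of 5%, 1.362 with cells thinned and 1.348 with TMM scaling. Over all ASPC-like cells it was 1.019, and 1.262, 0.842 and 0.884 under the first, second and last of these and 0.830 with each library clustered on its own. In B-like cells it was 2.406, and 6.102 with at least 1000 genes, and its interval reached 1 with a mitochondrial maximum of 5% and with cells thinned. The interferon list in B-like cells moved from percentile 99.58 to 39.80 with a mitochondrial maximum of 5% and to 0.02 with each library clustered on its own. The sphingolipid list in monocyte-like cells moved from 0.15 to 60.99 with cells thinned, and the vesicle biogenesis list in dendritic-like cells from 1.59 to 72.21 without barcodes of a second lineage. Apart from the unnamed committed cluster, the cause was not tested. Another 156 shares, Smpd3 ratios and counts of lists and named genes in the main classes stayed within the interval or within 1.5 times the count. Besides these 4 reversals, of the single lists followed and the counts in other classes 411 values kept their side, 40 percentiles came inside the range of random lists, 3 came outside it and 12 counts of lists outside the range moved by over 1.5 times. No paired analysis was possible because each group held 1 library, and for the same reason no replicate could be left out. Depth limits Smpd3 outside ASPC-like cells, with at most 38 UMIs in each class compared and library, and 52 in proliferating cells.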

Other observations

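The test of a subset of Dpp4-high cells was set out before its result was seen, for Smpd3 and for matrix genes. The tests of co-captured RNA, depth and the share of Dpp4-high cells were chosen after the result was seen. A cluster of dividing cells with Prg4 and Timp1 among its leading genes, of which 93.8% carried markers of ASPC, held 61 control cells (0.663%; 0.507 to 0.851) and 4 knockout cells (0.05%; 0.014 to 0.128). Prg4 and Timp1 were also lower in Dpp4-high cells of the knockout library. Interferon response genes lay apart between cell types, with medians of -0.33 (percentile 0.0) in committed ASPC-like cells and 0.36 (percentile 99.99) in endothelial-like cells without barcodes of a second lineage, a difference that was not tested. Over all endothelial-like cells the list lay inside the range at -0.06 (percentile 30.5), so that its place rests on the 66 knockout cells left. In those 66 knockout and 206 control cells Igtp stood at 107 against 35.7 CPM and Ifit1 at 124 against 58.9 CPM.

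Inflammatory cytokines and NF-kB targets had a median of -0.43 (percentile 0.02) in NK-like cells without barcodes of a second lineage, with Ccl3 at 119 against 180.2 CPM and Icam1 at 54.2 against 88.0 CPM. In monocyte-like cells on the same terms the cholesterol and fatty acid synthesis list had a median of 0.46 (percentile 99.5), against 0.38 inside the range (percentile 97.1) over all monocyte-like cells. Fabp4, a fatty acid binding protein that is not a member of that list, stood at 476.5 against 195.9 CPM on those terms. It leads the endothelial-like cluster, and its rise was not particular to monocyte-like cells. In B-, T-, NK- and Dpp4-high ASPC-like cells it was also higher in knockout, among the highest members of the lipid-associated macrophage list. Transcripts that were lower in knockout in all 7 classes included Gm42418, AY036118, Lars2 and Gm10076, the last with ratios of 0.217 to 0.371.

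Smpd3 was higher in Dpp4-high cells of the knockout library. Lymphocyte RNA in the same barcodes is argued against by its own low level of Smpd3. This was 3.56 CPM in knockout B-like and 0.98 CPM in knockout T-like cells, against 381 CPM in Dpp4-high cells. Such RNA dilutes the gene, so leaving out barcodes of a second lineage (lower bound 1.839) could not have removed the difference and decides nothing. Depth is argued against, with a lower bound of 1.148 at 1500 UMIs per cell. What stays open is a subset of activated control cells with low Smpd3, from a division of cells that took no account of Smpd3 but used genes chosen for being lower in knockout: the ratio was 0.914 (0.843 to 0.991) in cells without a UMI of Prg4, Cthrc1 or Timp1 (389 against 425 CPM) and 1.80 (1.63 to 1.99) in cells with one (362 against 201 CPM). Without barcodes of a second lineage as well, it was 1.07 (0.966 to 1.19) in cells lacking these UMIs, and in control the cells with one held less Smpd3. Whether the genotype or the individual sample lies behind the subset stays open and was not tested.

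Matrix genes were lower in ASPC-like cells of the knockout library. A lower share of Dpp4-high cells as the whole cause is argued against, since the median log2 ratio was -0.5509 within them. Lymphocyte RNA as the whole cause is argued against for Dpp4-high cells, with -0.3235 without barcodes of a second lineage (-0.23 over all ASPC-like cells). Since the median moved there from -0.5509, such RNA can still account for a part. For committed cells it is not argued against, as leaving out these barcodes took the median from -0.19 to 0.0565, inside the range. Open as well is the same subset for Dpp4-high cells, since cells were divided by genes chosen for being lower in knockout, of which Timp1 belongs to the list. The medians of -0.2655 (percentile 0.01) in cells without a UMI of Prg4, Cthrc1 or Timp1, and of -0.03 (percentile 1.01) with barcodes of a second lineage left out as well, lay below the range of random lists but therefore do not exclude it. The genotype stays open too and was not tested.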
